A study of Mus musculus with 4 samples.

How the data were processed

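Total RNA of Neuro2A cells carrying inducible Prox1 or GFP was made into 3′ messenger RNA libraries with a QuantSeq kit and sequenced on an Ion Proton instrument, per the labels' protocols. Libraries were made from RNA with an integrity number above 7, per the labels' protocols. Samples were put into the Prox1 or GFP group, with replicate numbers 1 and 2, from their titles.

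The deposited table of all genes gives, per library, the log2 of a normalised count plus 1, per the file headers and the values. Per the submitters' processing notes the authors used DESeq and the mm10 build; the aligner, the counting tool, its use of strand, the annotation release and any filter are not given in the sources used here. Undoing the log2 gave whole numbers for 100% of values, within a relative deviation of 3.47e-09, so the authors had rounded the normalised counts. The same table holds the authors' DESeq p-value, adjusted p and log2 fold change for 11933 of its 49548 genes, per the file headers. Each sample's own file holds the deposited signal, the normalised count divided by a length per gene, for 1860 genes, which are those with an authors' p-value under 0.05. Those files were used only to check the log2 values against them. Other sheets that repeat these values were not used here. No column of another sample was present. Coordinates and gene symbols are those of the authors' table, on mm10. Overlapping and antisense genes, and members of near-identical families, are uncertain in these counts.

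The planned test for raw counts did not apply, since the values were rounded after normalisation, and a count model was not run. log2(normalised count + 1) was tested with limma (lmFit, eBayes with a mean-variance trend; limma 3.58.1, R 4.3.3), Prox1 against GFP, on the 13290 genes with a mean of at least 10 normalised counts over the 4 libraries. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of low genes, so for named genes the text gives the ratio of mean normalised counts. A gene at 0 in both libraries of a group is given a bound against a floor of 3 counts per library, and a gene with 1 to 3 counts in a group a ratio with an exact 95% interval. Intervals and floors cover counting error only and treat normalised counts as reads.

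Reads behind the values were estimated from which whole numbers occur after rounding, which gave size factors of 1.0194 and 0.9706 for the Prox1 libraries and 0.8292 and 1.2492 for the GFP libraries. On 4 simulated libraries the estimate was off by at most 0.0229%. The factors correspond to an estimated 7440000 and 6600000 reads in the Prox1 libraries and 5910000 and 9600000 in the GFP libraries. There, 3 reads equal 2.94, 3.09, 3.62 and 2.40 normalised counts. Replicates differed by more than sampling noise (chi-square per degree of freedom 21.1 for Prox1 and 22.0 for GFP), so none was the other library sequenced again. This does not tell whether they came from separate cultures. On 13305 simulated genes of the Prox1 against GFP comparison with 200 changed, limma recovered 19% of 2-fold and 91% of 4-fold changes, with 3 false calls among 113. Every simulated gene had the same dispersion, the spread between replicates beyond counting error (0.0384). These rates therefore do not cover genes whose replicates vary more than that. The dispersion was set roughly and probably too high, which would lower the recovery.

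Before the data were examined, 30 gene lists were written from textbook knowledge, and the 28 with at least 5 tested members were tested with camera (preset correlation 0.01), adjusted over the lists. With an estimated correlation 0 lists passed after adjustment, and histones, glycolysis and catecholamine genes had an unadjusted p under 0.05. That correlation was estimated from only 4 libraries in 2 groups, so it is itself uncertain. Adjustment gave the same camera p of 0.411 to lists with unadjusted p from 0.0216 (histones) to 0.132 (immediate early genes), so this value does not rank them. With fry, which tests a list without comparing it with other genes, 7 lists passed. The list of 50 panel genes was written from general knowledge after the values had been seen. The rule for named genes, also written before the data were examined, took Prox1, the 10 largest rises and 10 largest falls among called genes with a mean of at least 50 in the higher group, no overlap of the groups' libraries and a proper gene symbol; in each list up to 2 members that rose most and 2 that fell most, or the member with the lowest p where none passed; Cdkn1b, Cdc25a and Ccnd1; and technical lists as groups. Other members named are marked as picked after their values were seen. Some genes that the rule names, and some lists, are not reported here.

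Alternatives were other scalings (TMM, written for this purpose, and cyclic loess), no filter or a mean of at least 50, pseudocounts of 5 and 0.5, the replicate number as a block, each library left out, limma without the trend or with vooma weights, other thresholds and other set tests. Added after seeing the data were a fit without the panel genes and the authors' adjusted p. Window and permutation tests and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.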

Results

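The data were 4 messenger RNA libraries from Neuro2A cells, a mouse neuroblastoma line. Of these, 2 came from a stable line that carries a doxycycline-inducible (Tet-On) Prox1 transgene and 2 from a stable line with inducible GFP in its place. Prox1 is a homeodomain transcription factor. Transgene expression was switched on with doxycycline at 1 µg/mL, and RNA was profiled with a 3′ messenger RNA library kit, which reads the end of each transcript. After the authors' normalisation the libraries summed to 7301259 (Prox1 replicate 1), 6798014 (Prox1 replicate 2), 7123722 (GFP replicate 1) and 7683100 normalised counts (GFP replicate 2). Between 18396 and 19811 genes were above 0 in each library. Log2 values of the 13290 genes tested correlated at r = 0.969 between the replicates of either group and at 0.901 to 0.915 between groups, across genes, which are not independent replicates. Nothing states that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Each transgene was in a line of its own, so line and transgene were not separable.

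The comparison asked what changes in neuroblastoma cells when Prox1 is induced, in a series titled for the action of Prox1 on axon outgrowth. Prox1 itself (ENSMUSG00000010175, mm10 chromosome 1, positions 190118035 to 190170714, minus strand) stood at 1304 and 2505 normalised counts in the Prox1 libraries, a mean of 1904.5 ± 849 (SD, n = 2). The GFP libraries held 2 and 3, a mean of 2.5 ± 0.71 (SD, n = 2), so the ratio of means was 762-fold. On the log2(normalised count + 1) scale the difference was 9.03 ± 0.36 (SE), with a limma adjusted p of 2.94e-08. Values at the gene do not tell transcripts of the transgene from those of the chromosomal copy. limma called 2124 of 13290 genes at an adjusted p under 0.05, of which 1006 rose and 1118 fell in Prox1 cells; 1488 of them differed at least 2-fold. In all 2124 the 2 groups' libraries did not overlap, as in 58.8% of tested genes, where chance gives 33.3%. In the authors' deposited table, DESeq passed 551 genes at the same adjusted threshold, 228 higher and 323 lower in Prox1 cells. Of these, limma called 539, all in the same direction. Many of the limma-called genes named below did not pass in that table, among them Nrxn3, Ephb4, Klf4, Ache, Vamp2, Nfasc and Ephb3 (DESeq adjusted p 0.0668 to 0.351). With any 1 of the 4 libraries left out, limma called 0 genes at the adjusted threshold (2461 unadjusted p under 0.05 without Prox1 replicate 1, 2844 without Prox1 replicate 2, 2981 without GFP replicate 1 and 2365 without GFP replicate 2), although no called gene changed sign. This covers each called gene named here, Prox1 included (adjusted p 0.142 to 0.246). The sign of a called gene could not change with a library left out, since the 2 groups' libraries did not overlap in any of them. Without the minimum count limma also called 0 genes (5032 with an unadjusted p under 0.05), and without the variance trend it called 1057, with 33 of the genes that the naming rule takes no longer past the threshold.

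**Figure D1:**
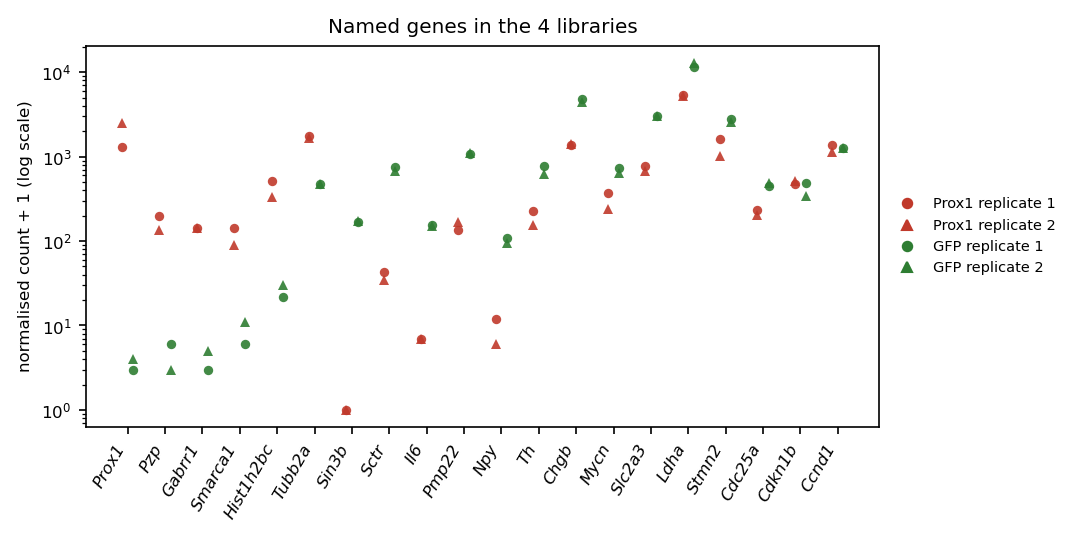
Normalised count + 1 on a log axis for 20 genes named in the text, 1 point per library, with Prox1 libraries in red and GFP libraries in green. Prox1 stands at 1304 and 2505 in its own libraries and at 2 and 3 in the GFP libraries, while the 4 libraries lie close together for Ccnd1.

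After Prox1, the largest rises among genes with at least 50 normalised counts in the higher group were in 9 genes. Prrg1, which encodes a membrane protein with a vitamin K-dependent domain, was at 44 and 70 in Prox1 cells and at 0 in both GFP libraries, at least 19.0-fold higher against a floor of 3 counts per library. Fthl17e, 1 of a family of near-identical ferritin-like genes whose reads are not separable with certainty, was at 46 and 61 against 0 and 0, at least 17.8-fold higher. The protease inhibitor Pzp rose from 3.5 ± 2.1 to 165.5 ± 46.0 and Gabrr1, a GABA receptor subunit, from 3.0 ± 1.4 to 142.0 ± 0.0 (SD, n = 2; limma adjusted p 5.82e-05 and 5.7e-05). Ifi203 stood at 71 and 72 against 2 and 1, a ratio of 47.7 with a 95% counting interval of 16.0 to 234. The chromatin remodeller Smarca1 rose 15.3-fold and Magel2, from an imprinted gene cluster, 12.7-fold. The histone genes Hist1h2bc and Hist1h2be were also in this set.

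The largest falls by the same rule included Kit, Met, Sin3b, Erbb4, Mir6939, Abl1, Adgrf4, Ly75 and Flnc. Of these, Kit, Met, Erbb4 and Abl1 belong to a set of 50 genes of a cancer hotspot amplicon panel, and Mir6939 lies within a further panel gene, Akt1 (mm10 chromosome 12, positions 112659277 to 112659351). The GFP libraries differed widely in several of them. Met was at 10 and 14834 normalised counts, Abl1 at 22765 and 557, Kit at 2215 and 734, Erbb4 at 68 and 232, and Mir6939 at 23 and 571. In the Prox1 libraries Met, Kit and Erbb4 were at 0, Mir6939 was at 0 and 1, and Abl1 at 77 and 71. Fold bounds against a floor of 3 counts per library were at least 492 for Kit and at least 50 for Erbb4. Panel genes were lower in Prox1 cells in 17 of 41 tested (41.5%), against 8.31% of the 13249 other genes. The panel was recognised from 8 of its genes, and among the 33 others tested 10 were lower (30.3%; Fisher's exact test, two-sided, p = 0.00025). On the normalised count + 1 scale, 9 of the 41 panel genes differed at least 4-fold between the 2 GFP libraries, against 87 of the other genes, and between the 2 Prox1 libraries 1 of 41 did. With precision weights (vooma) Met and Mir6939 no longer passed (adjusted p 0.369 and 0.0721). Without panel genes, a setting chosen after the data were seen, limma called 2158 of 13249 genes.

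**Figure D2:**
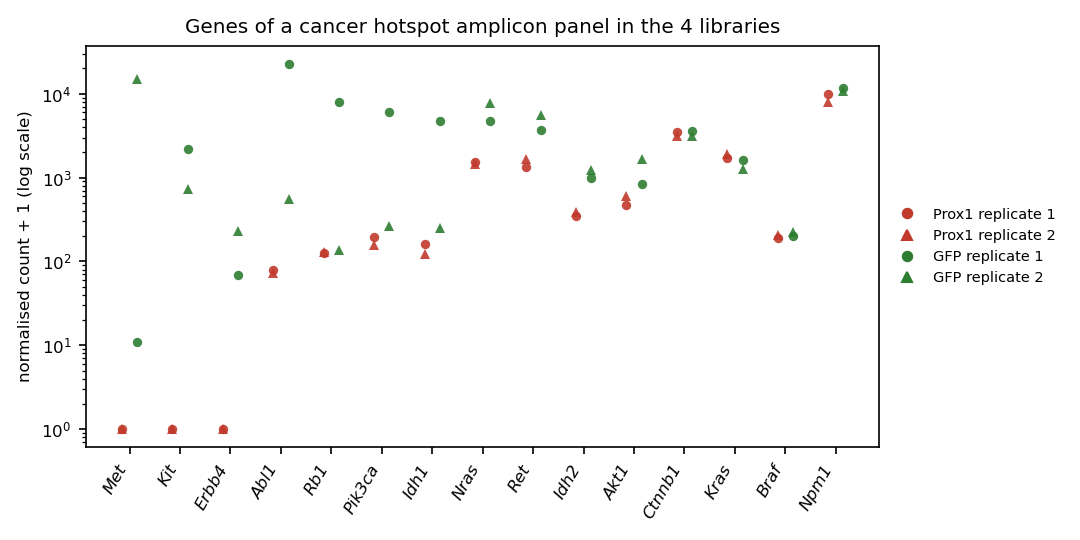
Normalised count + 1 on a log axis for 15 genes of the cancer hotspot panel, 1 point per library, chosen after their values were seen. Met, Abl1 and Rb1 differ widely between the GFP libraries (10 and 14834, 22765 and 557, 7934 and 137), while the Prox1 libraries lie close together.

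In the falling genes named outside the panel, other than Mir6939, the GFP libraries lay within 2-fold of each other. Sin3b, a scaffold of histone deacetylase complexes (mm10 chromosome 8, positions 72723285 to 72758201), was at 0 in both Prox1 libraries and at 166 and 172 in the GFP libraries, at least 56.3-fold lower. Ly75 fell from 137.5 ± 0.71 to 3.0 ± 0.0 and the actin crosslinker Flnc from 91.5 ± 31.8 to 2.0 ± 0.0 (SD, n = 2; limma adjusted p 4.58e-05 and 0.000174). Adgrf4 was at 0 and 2 against 66 and 93, a ratio of 79.5 with a 95% counting interval of 21.6 to 662. The next genes outside the panel, chosen after their values were seen, were Cyp2s1, the cytokine Il6, the secretin receptor Sctr, Amhr2 and Plekha2. Sctr fell 18.8-fold, from 713.0 ± 52.3 to 38.0 ± 5.7, and Il6 fell 25.1-fold, from 150.5 ± 2.1 to 6.0 ± 0.0 (SD, n = 2; limma adjusted p 1.78e-06 and 5.3e-05).

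Genes of the catecholamine and neuroendocrine list, which mark the sympathetic character of neuroblastoma, were mostly lower in Prox1 cells. Of 18 tested members 11 fell and 2 rose, and 12 and 2 did so adjusted over the list alone (median log2 fold change -1.06). The list passed camera at an adjusted p of 0.00063, with an adjusted p = 0.411 with an estimated correlation. Neuropeptide Y (Npy) fell 12.6-fold, from 100.5 ± 9.2 to 8.0 ± 4.2 (SD, n = 2), and acetylcholinesterase (Ache) 3.78-fold. Further members, picked after their values were seen, were the catecholamine-synthesis enzyme Th, at 228 and 155 against 779 and 616, and the granule protein Chgb, at 1390 and 1415 against 4795 and 4498. Cartpt rose 2.45-fold. In the list of neuroblastoma core and neurogenic transcription factors 12 of 31 tested members fell and 3 rose (12 and 4 adjusted over the list alone; median -0.43). Its camera adjusted p was 0.041, with an adjusted p = 0.411 with an estimated correlation. Without 1 library it was 0.0733 (Prox1 replicate 2), 0.0915 (GFP replicate 1) and 0.0724 (GFP replicate 2). Lmo1 fell 3.79-fold and St18 3.19-fold, Klf4 and Nr2f1 rose, and the oncogene Mycn, picked after its values were seen, stood at 372 and 238 against 739 and 632.

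In the axon lists, called genes went in both directions, and whether a list passed camera depended on the settings. Of 34 tested axon growth and growth cone genes 7 fell and 3 rose (10 and 5 adjusted over the list alone; median -0.28; camera adjusted p 0.138, and 0.0485 without the minimum count). Stmn4, which regulates microtubules, fell 2.57-fold and the adhesion molecule Nfasc 3.48-fold, while the tubulin Tubb2a rose 3.59-fold, from 477.0 ± 2.8 to 1714.5 ± 58.7, and Fez2 1.91-fold. Called members picked after their values were seen were Stmn2 at 1633 and 1020 against 2763 and 2559, Mapt at 1585 and 1703 against 2968 and 3134, and L1cam at 314 and 322 against 638 and 524. Of 27 axon guidance ligands and receptors 5 fell and 2 rose (8 and 3 adjusted over the list alone; camera adjusted p 0.071). This list passed by fry (adjusted p 0.0402) and by camera with a mean of at least 50 (0.00709). With an estimated correlation, at the minimum count used, its camera adjusted p was 0.411. Rgmb fell 6.45-fold and the semaphorin receptor Plxnd1 3.96-fold, while the ephrin receptors Ephb4 and Ephb3 rose from a mean of 3.0 ± 1.4 each to 28.0 ± 7.1 and 19.0 ± 0.0 (SD, n = 2). Of 32 synaptic vesicle and synapse genes 7 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p 0.0754, and 0.0258 without Prox1 replicate 2). Among them Syt4 fell 3.6-fold, Vamp2 rose 1.96-fold, and Nrxn3 was at 1 and 1 against 31 and 17, a ratio of 24 with a 95% counting interval of 6.29 to 204. Of 16 neurotrophin and differentiation signalling genes, which include the panel gene Ret, 5 fell and 2 rose (8 and 3 adjusted over the list alone; camera adjusted p 0.071, with 0.0258 without Prox1 replicate 2 and 0.0323 with a mean of at least 50), with Stra6 and Rara of retinoic acid signalling lower and Ngfr and Gfra1 higher.

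**Figure D3:**
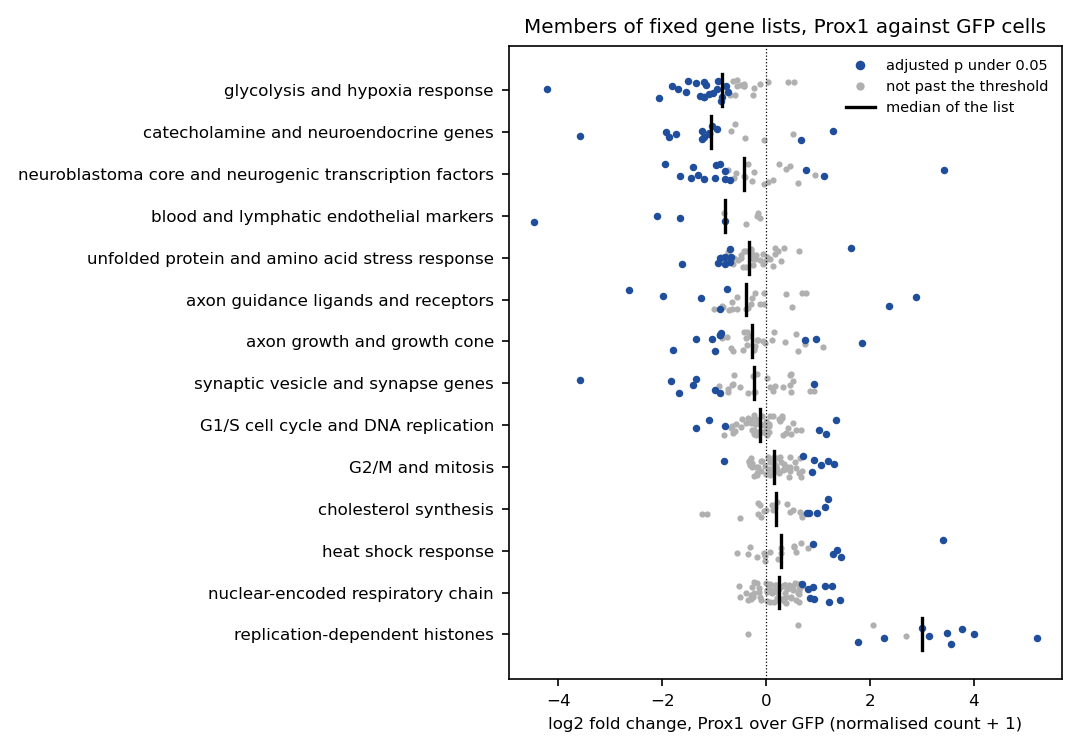
Log2 fold change of Prox1 over GFP for each tested member of 14 gene lists, 1 point per gene, in blue where the limma adjusted p is under 0.05 and in grey otherwise, with a black bar at the list's median. The medians run from -1.06 for the catecholamine and neuroendocrine list to 2.998 for the replication-dependent histones.

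Many glycolytic enzymes and hypoxia-responsive genes fell. Of 35 tested members 20 fell and 0 rose (24 and 0 adjusted over the list alone; median -0.84). The list passed camera at an adjusted p of 5.42e-09, with an adjusted p = 0.411 with an estimated correlation. The glucose transporter Slc2a3 fell 4.14-fold, from 3007.0 ± 2.8 to 725.5 ± 68.6 (SD, n = 2), and Ndrg1 was at 2 and 1 against 48 and 41, a ratio of 29.7 with a 95% counting interval of 9.83 to 147. Among members picked after their values were seen, Ldha was at 5406 and 5216 against 11446 and 12909, and Aldoa at 6185 and 7473 against 15436 and 25614. Of 75 nuclear-encoded respiratory chain genes 9 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.26), Uqcrfs1 2.62-fold and Ndufa5 2.33-fold. This list passed camera at an adjusted p of 0.0112, with an adjusted p = 0.592 with an estimated correlation and 0.132 without Prox1 replicate 1. Cholesterol synthesis genes rose in 5 of 24 cases and fell in 0 (7 and 1 adjusted over the list alone; camera adjusted p 0.108, and 0.0323 with a mean of at least 50), with Hmgcs1, an enzyme early in the pathway, 2.26-fold higher.

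Among cell cycle genes, those in the title of the reference cited for these lines differed in outcome. Cdc25a, a phosphatase that activates cyclin-dependent kinases, fell 2.14-fold, from 464.0 ± 29.7 to 217.0 ± 21.2 (SD, n = 2; limma adjusted p 0.00602). In the authors' deposited table its DESeq adjusted p was 0.0884. Cdkn1b, the inhibitor p27, did not pass, with 491.0 ± 24 in Prox1 and 415.5 ± 102.5 in GFP cells (SD, n = 2; limma adjusted p 0.477). The cyclin Ccnd1 did not pass either, with 1257.5 ± 174.7 against 1258.0 ± 7.1. Of 57 G1/S and DNA replication genes 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p 0.503), among them Pola2 upward and Rfc5 downward. Of 59 G2/M and mitosis genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p 0.071, with 0.0377 without GFP replicate 1 and 0.0392 with a mean of at least 50), with Ndc80 and Kif20a higher and Cenph lower. Of 27 cyclin-dependent kinase inhibitors and p53 targets, 3 of which are panel genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p 0.448).

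Replication-dependent histone genes rose in 9 of 13 tested cases and fell in 0 (11 and 0 adjusted over the list alone; median 2.998). The size of this median depended on the settings: it was 1.368 over all 39 members without the minimum count and 2.14 with a pseudocount of 5. The list passed camera at an adjusted p of 5.42e-09, with an adjusted p = 0.411 with an estimated correlation. Hist1h2bc rose 16.7-fold, from 25 ± 5.7 to 418.5 ± 126.6 (SD, n = 2), and Hist1h2be was at 49 and 54 against 1 and 0, a ratio of 103 with a 95% counting interval of 18.1 to 4107. These genes are close relatives, so the split of reads between them is uncertain. Of the 13 list members, 10 lay on chromosome 13 between positions 21782960 and 23751598 and 3 on chromosome 3. Further tested histone genes outside the list were 3 in the same stretch of chromosome 13, 0 of them called, and 3 on chromosome 3, which all rose. The 7 genes other than histones in the chromosome 13 stretch had a median log2 fold change of 0.74, and the chromosome's 460 tested genes had a median of 0.36. Heat shock genes rose in 5 of 21 cases and fell in 0 (6 and 0 adjusted over the list alone; median 0.29), with Hsph1 2.58-fold higher and Hspb1 at 17 and 24 against 1 and 1, a ratio of 20.5 with a 95% counting interval of 5.32 to 175. Their camera adjusted p was 0.0243, with an adjusted p = 0.411 with an estimated correlation, 0.0578 without Prox1 replicate 1 and 0.0535 without GFP replicate 2. Unfolded protein and amino acid stress genes fell in 8 of 42 cases and rose in 1 (11 and 2 adjusted over the list alone; median -0.34). Manf fell 3.05-fold, Ddit3 fell 1.91-fold, and Cth, an enzyme of cysteine synthesis, rose 3.04-fold. The camera adjusted p was 0.0201, with an adjusted p = 0.411 with an estimated correlation and 0.0769 without Prox1 replicate 1.

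The signalling lists did not pass camera at the minimum count used, but 2 of them did with a mean of at least 50. Of 25 immediate early genes 6 fell and 0 rose (6 and 0 adjusted over the list alone; adjusted p 0.071, and 0.0394 with that mean), with Arc 2.56-fold and Dusp5 2.11-fold lower. Of 26 Wnt pathway genes, 2 of them panel genes, 6 fell and 1 rose, and 7 and 1 did so adjusted over the list alone. The camera adjusted p was 0.0754, and 0.021 with that mean. Dkk3 was 3.15-fold lower and the receptor Fzd6 8.75-fold higher. Of 22 Notch pathway genes 2 rose and 1 fell (1 and 1 adjusted over the list alone; adjusted p 0.264). Of 26 TGF-beta and BMP genes, 1 of them a panel gene, 2 rose and 1 fell (1 and 1 adjusted over the list alone; adjusted p 0.343), with the activin antagonist Fst 7.42-fold lower. Of 25 apoptosis regulators 2 rose, Casp9 and Mcl1, and 1 fell, Bid (2 and 1 adjusted over the list alone; adjusted p 0.28). Of 18 interferon response genes 1 rose, Xaf1 by 4.74-fold, and 1 fell, Psmb8 by 3.03-fold (1 and 1 adjusted over the list alone; adjusted p 0.463). Of 79 cytosolic ribosomal protein genes 0 rose and 2 fell, Rplp0 and Rps2 (0 and 1 adjusted over the list alone; adjusted p 0.28, and 0.0209 without GFP replicate 1).

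Marker lists of other cell types had few members above the count minimum. Of 9 tested blood and lymphatic endothelial markers 4 fell and 0 rose (5 and 0 adjusted over the list alone; median -0.79, the same with Flt1 set at its bound). The growth factor Vegfc fell 4.37-fold, and Flt1 was at 0 and 0 against 16 and 28, at least 7.33-fold lower; a further called member, Fgfr3, is a panel gene. The camera adjusted p was 0.0039, with an adjusted p = 0.411 with an estimated correlation. Of 6 Schwann cell and glia markers 1 fell and 1 rose (1 and 2 adjusted over the list alone; camera adjusted p 0.495): the myelin protein gene Pmp22 fell 7.2-fold, from 1083.5 ± 10.6 to 150.5 ± 20.5 (SD, n = 2), and Ngfr rose 2.27-fold. For this list camera pointed up and fry, a test of the list alone, down. Of 6 fibroblast markers, 1 of them a panel gene, 1 fell, Sparc (1 adjusted over the list alone; camera adjusted p 0.0754, with 0.0277 without Prox1 replicate 1 and 0.0325 without panel genes). Of 5 lens genes 2 fell, the panel genes Fgfr1 and Fgfr2, and 1 rose, Crybb3 (2 and 1 adjusted over the list alone; camera adjusted p 0.511), with a median of -0.65 and a mean of 0.0044. With under 5 tested members, the mitochondrially encoded genes and the macrophage and leukocyte markers were not tested as lists.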

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

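The fit without the panel genes and the use of the authors' adjusted p were chosen after seeing the data. The number of calls depended on the settings. The 2124 called genes became 0 without a filter (limma, 5032 unadjusted p under 0.05, against 551 genes by the authors' DESeq), where 24187 genes were tested and Prox1 kept its log2 fold change of 9.03 at an adjusted p of 0.126. The prior degrees of freedom, the weight limma gives to the variance shared across genes, were 1.57 there and 10.89 in the main fit. Whether this alone accounts for the loss was not tested. Leaving out 1 library gave 0 calls in each of 4 fits, with a Prox1 log2 fold change of 8.56 to 9.50 at adjusted p 0.142 to 0.246; these fits have 1 residual degree of freedom fewer and assume that the lone library varies like the other group. Without the trend 1057 genes passed (533 higher, 524 lower), at adjusted p under 0.01 859 (368 and 491), and 551 did in the authors' deposited table (228 and 323). TMM (2230), cyclic loess (2374), pseudocounts of 5 (2238) and 0.5 (2067), vooma weights (2174), a mean of at least 50 (1903 of 9897) and no panel genes (2158) stayed within 1.5 times. In none of these fits did a called gene change sign. Only TMM and cyclic loess could have changed a sign, since the groups' libraries did not overlap in any called gene. The 1488 genes at least 2-fold apart were 708 higher and 780 lower. Same-numbered libraries did not deviate together (correlation -0.051), so the values gave no sign that the numbers pair them, which the labels leave unstated. With the replicate block 2528 genes passed (1216 higher, 1312 lower), 2115 of them shared, and Prox1 stayed at 9.03. The prior degrees of freedom were infinite there, so limma used only the variance shared across genes and not each gene's own. With the block 7 lists passed camera, the transcription factor list not (camera adjusted p 0.0571). Under a mean of at least 50, 14 lists passed in place of 8 (also axon guidance, neurotrophin, G2/M, Wnt, immediate early and cholesterol genes, at adjusted p 0.00709 to 0.0394, and at up to 0.125 to 0.297 in the other settings), and with an estimated correlation 0 (lowest adjusted p 0.411; 3 unadjusted under 0.05; 7 by fry). Over 13 settings the camera adjusted p ran from 0.00219 to 0.0915 for the transcription factor list, 0.0003013 to 0.132 for the respiratory chain, 0.0134 to 0.0578 for heat shock and 0.00278 to 0.0769 for the unfolded protein list, and stayed under 0.05 for the histone, glycolysis, catecholamine and endothelial lists. Ccnd1, not called in any fit, had a log2 fold change of -0.0075, which became 0.0404 under cyclic loess and ranged from -0.15 to 0.13 with 1 library left out. Whole reads were not recovered for all genes, so DESeq2 was not run. Depth limits low genes, since 3 reads equal 2.40 to 3.62 normalised counts.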

Other observations

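Tests on the panel genes, on S phase, on copy number at the histone genes and on windows with shared reads counted once were chosen only after the results were seen. Outside the lists, small nucleolar RNA genes fell in 34 of 177 tested cases and rose in 6 (median -0.34), while annotated antisense genes rose in 15 of 104 and fell in 4 (median 0.45). The use of strand in counting is not stated, so reads of a gene and its antisense partner are not separable. Along the genome, chromosome 13 had a median log2 fold change of 0.36 over 460 tested genes (97 rose, 17 fell) and chromosome 16 of 0.33 over 385 (66 and 12). Chromosome 7 stood at -0.23 over 1008 genes (42 and 117) and chromosome 5 at -0.17 over 902 (52 and 106). Of 8 segments of neighbouring genes that stood out, 3 lay on chromosome 13. A further segment on chromosome 18 (36559987 to 37654172) had a median of -0.36 and held 14 protocadherin alpha genes, which share their last exons and were all called lower, so that the same reads count several times among the calls.

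The genes of the cancer hotspot panel were high in the GFP libraries, and not evenly. Carry-over of amplicon libraries into the GFP libraries is a candidate explanation: without the 8 genes from which the panel was recognised, 3 of 33 panel genes (9.09%) were at least 4-fold apart between the GFP libraries on the normalised count + 1 scale, against 0.657% of other genes (Fisher's exact test p = 0.00142). Repression in Prox1 cells would not by itself set the 2 GFP libraries apart, so it does not account for that unevenness. For the lower level in Prox1 cells it cannot be told apart from carry-over: of the same 33 genes 10 were called lower. This was more often than in other genes (Fisher's exact test p = 0.00025), which both would give. Normalised counts do not show where reads lie within a gene. An exception is Mir6939, a short gene inside the panel gene Akt1. It was at 0 and 1 in the Prox1 and at 23 and 571 in the GFP libraries, but this is 1 gene. Of the 17 panel genes called lower, 6 were at least 4-fold apart between the GFP libraries (among them Abl1, Met, Idh1 and Pik3ca) and 11 were within 4-fold (Kit, Erbb4, Nras, Idh2, Ret, Src, Fgfr2, Fgfr3, Akt1, Smarcb1, Fgfr1). Panel genes took 1.25% and 0.862% of the GFP totals and 0.424% and 0.431% of the Prox1 totals.

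Replication-dependent histone transcripts usually lack a poly(A) tail, so their rise may come from more RNA without one. Other short RNAs did not rise with them, with a median log2 fold change of -0.297 over 227 genes (bootstrap interval -0.456 to -0.172). By kind the median was -0.34 in 177 small nucleolar and 0.192 in 45 small nuclear RNA genes (-0.416 to 0.5), both below the 2.998 of the histone list (1.368 over its 39 members without the minimum count). Reads at these genes may belong to longer overlapping transcripts with a tail, which the counts do not separate, so this does not decide the question. A larger share of cells in S phase is not borne out by the G1/S list, whose median was -0.113 (bootstrap interval -0.221 to 0.0043) where over 0.2 was needed. For list members past the count minimum, the values argue against a copy number difference that spans the chromosome 13 cluster and its neighbours as the whole cause. The 10 list members there had a median of 3.31 (bootstrap interval 2.06 to 3.77) and the 24 nearest genes other than histones 0.702 (0.403 to 0.879), and the segment that stood out there was at 0.524 without histone genes. The size of this gap at the cluster may depend on the count minimum, since the median over all 39 list members without it was 1.368. A difference confined to that cluster stays open, since the 7 other genes inside it had a median of 0.74 with a bootstrap upper bound of 2.47, within the interval of the histone genes; so does one on chromosome 3, with 3 list members (median 2.277, bootstrap lower bound 0.621) and the 24 nearest genes at 0.49 (0.29 to 0.894), and the cell line, the clone and Prox1 itself remain untested.

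Differences clustered along chromosomes: 103 of 12805 windows of 25 neighbouring genes lay beyond the 95th percentile of the highest median in 1000 shuffles of gene positions, 42 of them beyond the highest shuffle, and chromosome medians differed (permutation p 0.0001, the smallest that the permutations give). Without histone genes, and with protocadherin alpha genes and genes of identical values counted once, 61 windows lay beyond the same percentile of new shuffles, on chromosomes 1, 7, 13 and 19 and not on 3 or 18. The clustering could come from copy number differences between the 2 stable lines, a hypothesis that expression alone does not settle. The segments held 109 of the 2124 calls, so 2015 lay outside. Calls outside may still lie in shifted stretches, since chromosomes 5 and 16 held no segment and yet had medians of -0.17 and 0.33. The fall of glycolysis genes was tested against copy number differences too. The list's 20 called members lay among neighbours at a median of -0.002, which argues against copy number differences that span neighbouring genes as the cause. Changes confined to single genes were not tested. With the other scalings tried the highest list median was -0.768, so those scalings do not account for the fall.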
